A study of Mus musculus with 6 samples.

How the data were processed

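The data are single-cell RNA profiles of mouse embryonic fibroblasts carrying doxycycline-inducible lentiviral copies of Ascl1, Brn3b (gene symbol Pou4f2) and Isl1. Doxycycline was given from day 0 and neuronal medium with forskolin and FGF2 replaced serum medium on day 2. There are 6 libraries, 1 per day, called MEF (day 0), D2, D4, D7, D9 and D13. They were made with droplet chemistry that reads the 3' end of each transcript.

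The authors deposited 1 matrix of natural log values, ln(1 + UMIs per 10000), for 22314 genes and 48210 cells. Taking the exponential and subtracting 1 gave values that sum to 10000 in every cell, and 100% of them lay within 0.01 of a whole number of UMIs once scaled by the smallest value of the cell. Whole UMI counts were therefore recovered, and all sums, means and thinned counts come from them. Thinning had been planned on the condition that this recovery worked. The cell table lists 49088 barcodes, and the 878 without a column in the matrix were not analysed here.

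The submitters' processing notes name CASAVA 1.8, fastp, Cell Ranger 3.0.0, Seurat 2.3.4 and the mm10 build. The order of the steps, their parameters and the cell filters are not given in the sources used here. Reads were not aligned again. Gene positions come from GENCODE mouse release M21 on mm10, a copy that may not be the annotation the authors used, and it holds 21853 of the matrix symbols.

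The libraries hold 6514, 6937, 6952, 5642, 10882 and 11283 cells in day order. Their median UMIs per cell are 20399.5, 19527, 16747, 16020, 15708 and 14982, and their median detected genes are 4447, 4735, 4453, 4479.5, 4142 and 4207. No cells were removed. The matrix as used here holds 0 mitochondrially encoded genes, so the mitochondrial part of the planned cell filter had nothing to act on.

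The level of a gene in a library is the mean over cells of UMIs per 10000. Genes with a mean of at least 0.1 in at least 1 library were kept, which leaves 10243. A log2 fold is taken after adding 0.05 UMIs per 10000 to both levels. A gene is called higher or lower when its fold is 2 or more in size. Where 1 library has 0 UMIs, the fold is given as a bound against a floor of 3 UMIs in that library.

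With 1 library per day there are no replicates, and no test, p value or genome-wide count of differing genes is given. Intervals are exact Poisson intervals for UMI counts and exact binomial intervals for shares of cells, at 95%. They cover counting error only and say nothing about differences between cultures made on other occasions. For the 144 named genes with at least 100 UMIs in both libraries, counting error of the pooled UMI ratio reaches 0.30 log2 units at most. For the 23 with fewer it reaches 3.89. The added 0.05 is no part of this error. It holds the log2 fold of any gene that is low in a library toward 0, also among the 144. For D13 over MEF, Actg2 was at -4.82 as reported and -7.46 from pooled UMIs, and Isl1 at 0.55 and 2.41. Snap25, with 1 UMI in MEF, is given as a level.

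Gene lists, cell markers, comparisons and the rule for naming genes were fixed before the data were examined. The rule names 12 genes in each direction for D13 over MEF and 6 for each other comparison, ranked by log2 fold among genes with at least 0.5 UMIs per 10000 in a library. Predicted genes, ribosomal protein genes and Rik symbols were passed over. It also names the 4 members of each list with the largest D13 over MEF folds.

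The 39 lists hold 509 genes, of which 485 are in the matrix and 337 were kept. A list is described by the median log2 fold of its kept members and by the number of members higher and lower. Its percentile is its place among 10000 random lists matched to it by expression in 20 bins (seed 1), given for lists with at least 5 kept genes. The percentile describes how unusual the list is among genes of similar level and is not a test. Members with 0 UMIs in a library enter the median with the added 0.05, and a median taken with such members at their bound is given where it differs by over 1.5-fold.

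For shares of cells, every cell was thinned at random to 3000 UMIs so that depth could not set the share. Cells below that depth, 1546 in all, were left out of these shares, and 46664 were used. A cell counts as having the markers of a class when at least 3 of them have a UMI. The neuron, fibroblast, skeletal muscle, cycling and retinal ganglion cell (RGC) classes have 12 markers each. Shares for the interferon list and for 6 immediate-early genes (Fos, Fosb, Egr1, Jun, Junb, Ier2) were added after the data had been seen. Sets with fewer than 20 cells were given no share.

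Delivered factors were counted per cell as the number of Ascl1, Pou4f2 and Isl1 with a UMI after thinning. Delivered and endogenous copies cannot be separated, because both carry the same gene symbol, and a 3' tag may miss a vector whose transcript ends in vector sequence. Counts of delivered factors are therefore counts of detection.

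Cells of all libraries were also clustered together: natural log values, 2000 variable genes, scaling limited to 10, 30 principal components, 15 neighbours and Leiden resolution 0.5. A cluster was named only when at least 3 fixed markers of 1 class stood out in it. Beyond the planned rule, it was left unnamed where its 10 leading genes held more markers of another class, or where its cells had under 1/3 of the median depth of their libraries and its leading genes held no marker of its class. In the main clustering these limits left out 2 shallow clusters, 1 with 12 neuron markers and 1 with 4 cycling markers. Clustering was repeated at resolutions 0.3 and 1.0, with 15 components, without the 3 delivered factors, and without any marker gene.

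Scrublet called 3, 1, 5, 7, 0 and 0 cells as doublets in day order. That is far too few for libraries of this size, so the caller had not worked and nothing was removed on its calls. Doublets were weighed in another way, added after the data had been seen. Cells with both Xist and Y-linked UMIs were counted among cells with both neuron and fibroblast markers, among cells with 1 of the 2 kinds, and among random pairs of cells added together.

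The fold, list and thinning steps were also run on simulated counts with known answers, 1000 cells per library. Of the 200 genes set to differ, 60 lay 1.5-fold apart, and 0% of these were called while 100% had the right sign. The 73 genes set 3-fold apart and the 67 set 8-fold apart were called in 100%, and the 7460 unchanged genes in 0%. The added value keeps a 3-fold difference from being called in genes whose lower level is under that value. The rates for changed genes therefore do not carry over to such genes, among them many neuronal genes in MEF. The simulated rates also say nothing about differences between cultures made on other occasions. A raised list lay at percentile 100, and of 100 unchanged lists 3 lay above the upper 5% line and 5 below the lower. Thinning returned 99.8% of the expected UMIs.

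Each result was recomputed with an added value of 0.5 or 0.01, with other gene filters, with pooled sums, with folds centred on the median gene, with the difference of mean natural log values, with other marker numbers and depths, and with other clusterings.

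The software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5 (which includes Scrublet), anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. Velocity and trajectory models, transcription factor target scores and comparison with primary retinal cells were left out.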

Results

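Single-cell transcriptomes were collected from mouse embryonic fibroblasts (MEF) on the way to neurons resembling retinal ganglion cells (RGCs), the projection neurons of the retina. The cells carried doxycycline-inducible Ascl1, Pou4f2 (Brn3b) and Isl1. Ascl1 is a proneural factor, and Pou4f2 and Isl1 act together in RGC development. The 6 groups were MEF at day 0 and cells after 2, 4, 7, 9 and 13 days of induction (D2, D4, D7, D9, D13), with 1 library each. There were 6514, 6937, 6952, 5642, 10882 and 11283 cells in day order. The libraries held 141060289, 144847531, 133432248, 104599948, 197532428 and 195445652 UMIs. Differences between days could not be held against a spread between replicates, so they are given as sizes, and a gene is called higher or lower from 2-fold on.

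The 3 delivered factors were absent or rare at day 0 and at their highest levels at day 2. Ascl1 was the most abundant on every day after induction, and all 3 were far lower at days 9 and 13 than at day 2. The course was not smooth, because each was lower at day 4 than at day 7.

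Ascl1 (chromosome 10, 87490819 to 87493660 on mm10) had 0.001 UMIs per 10000 in MEF and 41.2, 12.3, 24.7, 2.41 and 0.374 from D2 to D13. Pou4f2 (chromosome 8, 78433010 to 78436645) had 0 UMIs in MEF, which allows up to 0.0566% of cells with a UMI. It reached 4.26 at D2, at least 16431-fold over MEF, and 1.03, 1.64, 0.174 and 0.031 on the later days. Isl1 (chromosome 13, 116298281 to 116309689) went from 0.010 in MEF to 2.28, 0.910, 1.25, 0.194 and 0.038. Ascl1 UMIs were found in 0.184% of MEF and in 89.0%, 76.3%, 75.1%, 40.1% and 32.0% of cells from D2 to D13. For Pou4f2 the shares after day 0 were 70.3%, 41.8%, 43.7%, 13.0% and 4.56%, and for Isl1 they were 61.1%, 42.1%, 41.4%, 13.0% and 4.98%, against 1.30% in MEF. After thinning to 3000 UMIs the Ascl1 shares were 0.032%, 73.3%, 58.5%, 55.4%, 19.8% and 9.50% in day order. The thinned Pou4f2 shares from D2 on were 42.1%, 17.7%, 25.1%, 3.59% and 0.814%, and the thinned Isl1 shares 29.8%, 16.3%, 21.1%, 4.35% and 1.25%. The MEF shares are the background for these genes before induction, at a median of 20399.5 UMIs per cell against 14982 at D13. They do not measure free factor RNA in droplets of the later libraries, which was not estimated. Endogenous and delivered transcripts could not be told apart.

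**Figure D1:**
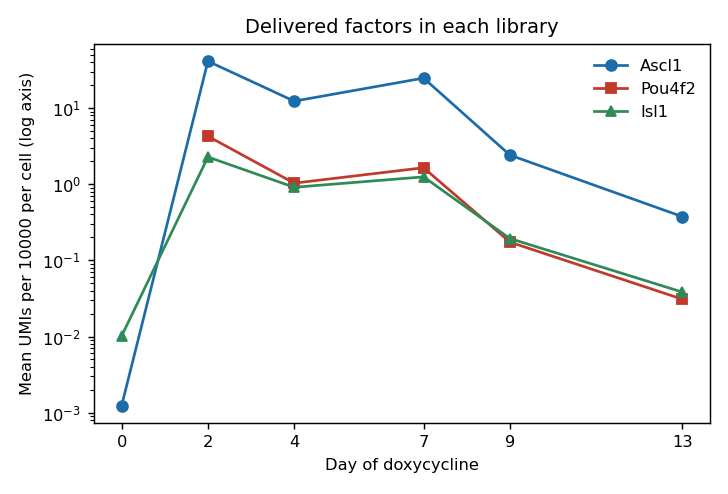
Mean UMIs per 10000 (log axis) of Ascl1, Pou4f2 and Isl1 against day, 1 library per day; Pou4f2 had 0 UMIs at day 0 and is not drawn there. All 3 peak at day 2 (Ascl1 41.2) and are lowest after induction at day 13 (0.374 for Ascl1).

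The comparison of D13 with MEF asks what separates the end of the culture from its start. The D13 cells had much less of the contractile and proliferative programmes of cultured fibroblasts. They had more extracellular matrix RNA, more immediate-early RNA, and somewhat more neuronal RNA over the whole library. Lists for glycolysis were lower, and lists for interferon response and cAMP-responsive genes were higher. The median gene stood 0.22 log2 units above MEF, a shift of scale against which list medians can be read.

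The 12 most raised genes were led by Agtr2. Agtr2, an angiotensin receptor, went from 0.003 to 4.99 UMIs per 10000 (log2 fold 6.57), Ogn from 0.188 to 21.6 (6.50), and Dcn (chromosome 10, 97479609 to 97518143) from 0.577 to 52.9 (6.40). Igf1 went from 0.051 to 7.25 (6.17) and Dhrs3 from 0.033 to 4.21 (5.69). Fos (5.601) and Fosb (5.55) reached 7.14 and 4.26. The rest were Islr (5.33), Lum (5.29), Tmem119 (5.26), Aspn (5.24) and Capn6 (5.20).

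The 12 most lowered genes were led by Serpine1, a protease inhibitor. Serpine1 went from 8.88 to 0.021 (-6.98), Ankrd1 from 5.03 to 0.032 (-5.95) and Lgals3 from 3.22 to 0.017 (-5.62). Tagln (chromosome 9, 45929619 to 45936058) went from 53.4 to 1.04 (-5.61), S100a4 from 5.23 to 0.104 (-5.10) and Acta2 from 45.0 to 1.33 (-5.03). Actg2 (-4.82), Tnc (-4.67), Il1rl1 (-4.62) and Ptgs2 (-4.58) followed, and Cav1 went from 3.47 to 0.099. Lce1h went from 1.09 to 0 UMIs, 7603-fold lower against the floor of 3 UMIs.

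Fibroblast matrix genes and smooth-muscle contractile genes stood on opposite sides of MEF. Of 24 fibroblast genes 13 were higher and 2 lower, with a median log2 fold of 1.73 (percentile 100), and Col3a1 went from 1.14 to 34.4 (4.86). All 9 contractile genes of smooth muscle were lower, with a median of -3.08 (percentile 0), among them Ctgf (-3.77). Skeletal muscle genes had a median of 0.80 (10 of 22 higher, percentile 98.5), led by Tnnc2 (3.09), Myl1 (2.90), Tnnt3 (2.56) and Tnni2 (2.37). Adipocyte and cartilage genes were at -0.97 (percentile 0.66, 5 genes), with Col2a1 at -3.97, Fabp4 at -1.71, Runx2 at -0.97 and Lpl at 1.53. Regulators of the mesenchymal state were near the median gene at 0.14 (percentile 55.0), with Cdh2 at -1.30, Snai2 at -0.87, Twist2 at 0.85 and Zeb1 at 0.996.

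Neuronal lists had medians above that of all genes in the D13 library as a whole. Of 18 pan-neuronal genes 13 were higher and 1 lower (median 1.62, percentile 100). Stmn2 went from 0.492 to 2.59 (2.28) and Rtn1 had a log2 fold of 2.64. Stmn3 went from 0 to 0.503 (5007-fold over the floor of 3 UMIs), and Snap25 went from 1 UMI in MEF to 0.187 per 10000. Synaptic genes had a median of 1.79 with 13 of 14 higher, including Syt4 (3.40), Nrxn1 (3.03) and Stx1b (2.12). Ion channel and receptor genes had a median of 1.07 (6 of 12 higher, percentile 99.05), with Gabra3 at 3.37, Gria2 at 1.84, Kcnb1 at 1.79 and Cacna2d1 at 1.71. Axon guidance genes were at 0.97 (percentile 99.2), with Epha5 at 3.06, Ephb2 at 2.80 and Unc5b at -2.23, while Robo2 reached 0.406 UMIs per 10000 from 0.033. Neural splicing regulators were at 0.46 (percentile 71.0), with Rbfox1 at 1.07, Rbfox2 at 0.77, Celf5 at 0.72 and Ptbp1 at -0.76. The many neuronal genes below 0.05 in MEF have folds held down by the added 0.05, and with 0.5 added the pan-neuronal median was 0.34 and the synaptic median 0.41.

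Cell-type lists of the retina and nervous system had medians below those of the pan-neuronal and synaptic lists. RGC genes had a median of 0.64 (7 of 19 higher, 1 lower, percentile 96.5), with Nefl at 2.14, Elavl4 at 1.91 and Ebf3 at 1.84. Early neurogenic factors were at 0.59 (percentile 86.6), with Cbfa2t3 at 1.99, Cbfa2t2 at 1.06, Dll3 at 0.85 and Zbtb18 at 0.76. Notch response genes were at 0.40 (percentile 58.7; Hey1 2.00, Notch3 1.71, Hes1 0.40, Notch1 -0.38). Somatosensory genes were at 0.69 (percentile 90.0), and Ntrk2 went from 0.007 to 1.55 (4.82), with Ntrk3 at 2.77, Calca at 2.75 and Six1 at 0.218 per 10000 from 0.079. Müller glia genes were at 0.99 (percentile 97.3), with Apoe going from 0.378 to 4.96 (3.55), Slc1a3 at 2.54, Dkk3 at 2.15 and Vim at -2.44. Amacrine and horizontal genes were at 0.76 over 4 genes, with Slc6a9 at 1.26, Onecut2 at 0.47 and Prox1 at 0.32. Calb1, with 0 UMIs in MEF, was 448.2-fold over the floor of 3 UMIs. Bipolar genes were at 0.65 (Prkca 0.75 and Isl1 0.55), motor neuron genes at 1.06 (Slc5a7 2.01; Lhx3 0.004 per 10000), and neural progenitor genes at 0.39 (Msi1 0.77, Prom1 0.39, Nes -3.32). The factor list, 3 genes with Pou4f2 at 0 UMIs in MEF, had a median of 0.69, or 3.05 with Pou4f2 at its bound. With members at 0 UMIs in MEF set to their bounds, the ion channel median was 1.46, the early neurogenic median 0.65, the amacrine and horizontal median 0.86 and the pan-neuronal median 1.62. The only glutamatergic gene kept, Gls, was at 0.23. The photoreceptor, GABAergic, Schwann cell, erythroid and mitochondrially encoded lists had 0 kept genes.

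Cell cycle lists were lower on the median. All 20 G2/M genes were lower (median -2.24, percentile 0), led by Birc5 (-3.60), Ube2c (-3.26), Top2a (-2.90) and Ccna2 (-2.72). Of 19 S-phase genes 15 were lower and 4 within 2-fold (median -1.51), with Rrm2 at -4.21, Mcm5 at -2.22, Clspn at -2.22 and Uhrf1 at -2.20. Cyclin-dependent kinase inhibitors and p53 targets split, 5 of 15 higher and 6 lower (median 0.68, percentile 97.3). Cdkn1c went from 1.32 to 22.4 (4.03), with Cdkn1b at 2.63, Cdkn2a at 2.36 and Mdm2 at -2.09.

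Among response and metabolic lists, cAMP and CREB targets stood highest. Their median was 2.35 (10 of 13 higher, percentile 100), with Pde4b at 3.50, and Scg2 and Vgf reaching 0.403 and 0.807 UMIs per 10000. Forskolin, an activator of cAMP synthesis, was in the neuronal medium, but its part in this was not tested. The list was already raised at D2, the day of the switch to that medium. Its median fold for D4 over D2 was negative. Immediate-early and stress genes had a median of 1.10 (6 of 12 higher, percentile 99.9). Egr1 went from 0.390 to 7.62 (4.12) and Ier2 was at 2.39. Of the heat-shock genes in this list, Hspa1a was at 0.66 and Hsp90aa1 at -2.04, and no median was taken for them as a group. Interferon genes had a median of 1.27 (7 of 11 higher, percentile 99.8), with Ifi27l2a at 3.45, Oasl2 at 2.09, Bst2 at 1.73 and Isg15 at 1.39. Endoplasmic reticulum stress genes were at 0.93 (percentile 98.3; Trib3 2.75, Ddit3 1.34, Herpud1 1.07, Dnajb9 1.05). Cholesterol synthesis was at 0.39 (percentile 75.3; Insig1 1.70, Hmgcs1 1.32, Srebf2 0.63, and Idi1 at 0.399 per 10000 from 0.223). Glycolysis was at -1.39 (7 of 13 lower, percentile 0), with Eno1 at -2.65, Pkm and Pgk1 at -2.26 and Ldha at -2.10. Oxidative phosphorylation was at -0.43 (percentile 21.5; Cox5a -1.57, Uqcrc1 -1.01, Uqcrq -0.97, Ndufb8 -0.72).

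Lists of possible bystander cells in the starting culture had few kept genes. Lyz2, the only macrophage gene kept, was at -2.78, endothelial genes at -0.52 (Flt1 -3.94, Egfl7 -0.52, Kdr -0.18), and epithelial genes at -1.24 (Krt19 -4.01, Krt8 -1.24, Krt18 -0.29).

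**Figure D2:**
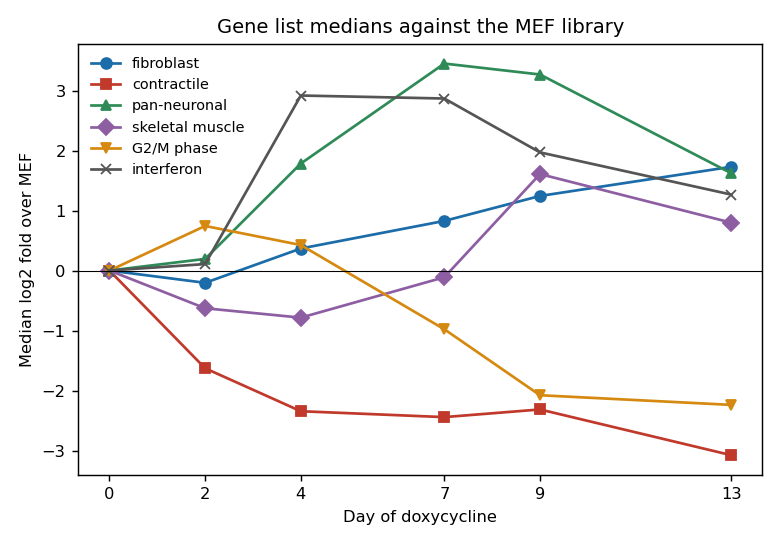
Median log2 fold over MEF of 6 gene lists against day, 1 library per day. Contractile genes stand below MEF on every later day (-3.08 at day 13), the pan-neuronal list peaks at day 7 (3.45), and the interferon list at day 4 (2.92).

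The comparison of D2 with MEF asks what the first 2 days of factor expression, still in serum medium, set apart. Contractile genes were already lower and a first set of neuronal and neurogenic genes was higher, but most pan-neuronal genes were not. The G2/M list stood above the median gene, with few of its genes past 2-fold. The median gene stood 0.17 above MEF.

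Besides the factors themselves (Ascl1 9.65, Isl1 5.27), Gal, the neuropeptide galanin (chromosome 19, 3409915 to 3414544), went from 0.006 to 18.1 UMIs per 10000 (8.33). Il11 went from 0.095 to 3.42 (4.58) and Mcpt8 from 0.051 to 1.73 (4.14). The lowest were Ctgf, from 10.1 to 0.572 (-4.03), F3, from 3.07 to 0.235 (-3.45), Serpine1 (-3.01), Lce1h (-3.01), Cdc42ep3, from 4.25 to 0.494 (-2.98), and Gadd45b, from 1.61 to 0.170 (-2.92). The factor list had a median of 6.43, or 9.65 with Pou4f2 at its bound. Members at 0 UMIs in a library, set to their bounds, gave medians of 0.24 for pan-neuronal genes, 0.83 for early neurogenic factors and -0.69 for skeletal muscle genes.

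Of 18 pan-neuronal genes 5 were higher and 1 lower (median 0.19, percentile 60.7): Stmn2 (2.98), Gap43 (2.35), Tubb3 (1.69), Nefm (1.51) and Nefl (1.16) were higher. Snap25 stood at 0.010 UMIs per 10000 and Syt1 at 0.041. RGC genes had a median of 0.34 (8 of 19 higher), most of them shared with that set. Early neurogenic factors had a median of 0.50 with 4 of 12 higher, namely Hes6 (2.56), Dll3 (2.41), Sox11 (2.04) and Zbtb18 (1.06), and Cbfa2t3 close below. Of 9 contractile genes 8 were lower (median -1.63), and of 22 skeletal muscle genes 6 were lower (median -0.63, percentile 0). G2/M genes had a median of 0.74 (3 of 20 higher, percentile 99.99), with Mki67 at 1.54, and S-phase genes 0.36 (1 of 19 higher, percentile 84.5). The cAMP list was at 1.42, on the day of the switch to forskolin medium, and cholesterol synthesis was at 0.69 (5 of 16 higher; Insig1 2.47). Fibroblast genes stood at -0.20, interferon genes at 0.11 and immediate-early genes at 0.28.

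Between D2 and D4 neuronal medium was introduced. Interferon-response RNA was higher for all 11 kept genes of its list of 12, and the medians of the pan-neuronal, RGC and somatosensory lists were near or above 2-fold. The factors were lower, and so were some immediate-early and cAMP-responsive genes. The median gene differed by 0.07.

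All 11 interferon genes were higher, with a median of 2.81: Isg15 (chromosome 4, 156199424 to 156200818) went from 0.069 to 2.58 UMIs per 10000 (4.47), Ifi27l2a from 0.181 to 6.03 (4.72), and Ifit1 was at 3.60. Of 18 pan-neuronal genes 10 were higher (median 1.21), with Elavl3 at 2.72, Elavl4 at 2.57 and Map2 at 1.96. RGC genes had a median of 0.998 (9 of 19 higher, 2 lower), with Ebf1 at 1.64, Ebf3 at 1.49, Pou4f1 at 1.38 and Rbpms2 at -1.01. Somatosensory genes had a median of 0.86 (6 of 12 higher), with Calca at 2.81, Prrxl1 at 2.78 and Scn9a at 2.17, and early neurogenic factors had 0.74 (Dll3 1.96, Myt1 1.799). Besides interferon genes the most raised were Pvalb, from 0.048 to 1.38 (3.87), Ogn, from 0.134 to 2.54 (3.82), Mfap4, from 0.122 to 2.11 (3.65), and Pcp4, from 0.003 to 0.596. The most lowered were Il11 (-4.71), Serpine1 (-3.97), Ptgs2 (-3.799), Il1rl1 (-3.58), Hbegf (-3.38) and S100a4 (-3.35). The cAMP list was at -0.88 (3 of 13 lower) and the immediate-early list at -0.84 (4 of 12 lower), with Egr1 at -1.96.

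From D4 to D7 most pan-neuronal genes and 7 of 14 synaptic genes were higher, while most G2/M genes and 7 of 13 glycolysis genes were lower. Some matrix genes were higher. The median gene differed by 0.07.

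Pan-neuronal genes had a median of 1.38 (11 of 18 higher, 0 lower), with Ina going from 0.085 to 0.846 (2.73), Rtn1 at 2.68, Stmn3 at 2.67 and Snap25 at 2.04. Synaptic genes had a median of 1.03 (7 of 14 higher) and ion channel genes 1.04 (6 of 12 higher; Kcna2 2.15, Gria2 1.66). RGC genes stood at 0.42 (2 of 19 higher). Of 20 G2/M genes 16 were lower (median -1.24; Ube2c -2.03), and of 13 glycolysis genes 7 (median -1.02; Pgk1 -1.64, Pkm -1.35). Fibroblast genes had a median of 0.63 (7 of 24 higher, 2 lower and 15 within 2-fold; Dcn 1.97, Postn 1.94). The most raised were Hrk, from 0.027 to 0.791 (3.45), Eln, from 0.316 to 3.43 (3.25), Apoe (2.82), Ecel1 (2.79) and Prss35 (2.75). The most lowered were Spp1, from 18.6 to 0.575 (-4.90), Gal, from 2.72 to 0.186 (-3.555), Ankrd1 (-3.32), Fabp4 (-2.60), Cst6 (-2.48) and Mcpt8 (-2.33).

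From D7 to D9 most skeletal muscle genes and some immediate-early genes were higher, and the delivered factors and 6 of 12 early neurogenic factors were lower. Pan-neuronal genes were on balance level. The median gene differed by -0.17.

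Of 22 skeletal muscle genes 17 were higher (median 1.74). Mylpf (chromosome 7, 127208890 to 127214298) went from 0.096 to 2.78 UMIs per 10000 (4.28), Acta1 from 0.037 to 0.800 (3.29), Tnnc2 from 0.058 to 0.887 (3.12) and Myl4 from 0.058 to 0.812 (2.997), whereas Myod1 was at -0.85. Fosb went from 0.150 to 3.74 and Fos from 0.397 to 5.70 (3.69), and the immediate-early list had a median of 0.83 (5 of 12 higher). Early neurogenic factors were lower for 6 of 12 (median -0.93; Dll3 -2.18, Myt1 -1.37, Hes6 -1.32), and somatosensory genes had a median of -0.63 (Prrxl1 -1.94). Ascl1 (-3.33), Pou4f2 (-2.92) and Isl1 (-2.41) were among the most lowered genes, with Miat, from 3.83 to 0.420 (-3.05), Btbd17, from 0.594 to 0.028 (-3.04), and Nt5dc2, from 3.32 to 0.590 (-2.40). Pan-neuronal genes had a median of -0.14 (1 of 18 higher and 3 lower), with Mapt at 1.06, Nefm at -1.70 and Map2 at -1.04. Of 20 G2/M genes 12 were lower (median -1.12).

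From D9 to D13 most pan-neuronal genes were lower in the library as a whole. Some interferon and contractile genes were lower too. The median gene differed by 0.04.

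Of 18 pan-neuronal genes 13 were lower and 0 higher (median -1.62). Tubb3 went from 2.51 to 0.328 (-2.76), Ina from 0.901 to 0.125 (-2.44), Rtn1 from 1.96 to 0.327 (-2.41) and Crmp1 from 0.590 to 0.075 (-2.36). Synaptic genes stood at -0.53 (3 of 14 lower), early neurogenic factors at -0.91 (Myt1 -1.75), interferon genes at -0.94 (5 of 11 lower; Bst2 -1.66) and contractile genes at -0.81 (3 of 9 lower; Acta2 -2.69). Ascl1 was lower again (-2.54). The cAMP list stood at 0.54 (2 of 13 higher), with Nr4a2 going from 0.149 to 0.661 (1.83). The other most raised genes were Tmem119, from 0.989 to 4.99 (2.28), Pnoc, from 0.095 to 0.558 (2.07), Chrdl1, from 0.164 to 0.710 (1.83), Arrdc4, from 0.335 to 1.29 (1.801), and Enpp1, from 0.119 to 0.510 (1.72).

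Shares of cells tell how many cells carried each programme. Cells with neuron markers were most frequent at day 7 and few at day 13, and cells with fibroblast markers were the great majority on every day. After thinning to 3000 UMIs, at least 3 of 12 neuron markers were found in 0.143% of MEF and in 6.86%, 15.3%, 25.9% (24.7 to 27.1), 15.3% and 3.02% of cells from D2 to D13. Without thinning the shares were 8.26%, 42.4%, 51.3%, 47.7%, 36.0% and 15.7%, and the peak was then at D4, as it was with 2 markers required (38.3%). Cells near the threshold, with 2 or 3 neuron markers, were 36.7% of D2, 32.2% of D4 and 7.83% of D9, while 13.3% of D7 had 6 or more. At D2 the share rests on cells with exactly 3 markers (6.49%), and with 4 required it was 0.369%.

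Fibroblast markers were found in 96.6%, 93.2%, 90.3%, 81.1%, 90.1% and 98.3% of cells in day order (97.3%, 95.4%, 96.8%, 93.3%, 98.7% and 99.8% without thinning). Both kinds together were found in 0.143%, 6.66%, 9.96%, 8.97%, 6.22% and 1.79% of cells (8.24%, 42.1%, 49.5%, 42.1%, 34.9% and 15.6% without thinning). Among D9 cells with both, 30.4% also had Xist and Y-linked UMIs together, against 9.57% of cells with fibroblast markers only and 51.4% of random pairs of cells. At D4 these shares were 7.49%, 6.89% and 49.8%. Skeletal muscle markers were found in 0.207%, 0.200%, 0.045%, 0.442%, 1.58% (1.36 to 1.84) and 0.732% of cells. Without thinning their highest share was at D2 (5.45%, against 4.63% at D9). Cycling markers were found in 31.6%, 45.9%, 26.5%, 7.62%, 2.40% and 1.43% of cells, and in 54.6%, 71.6%, 45.9%, 15.8%, 5.26% and 3.65% without thinning.

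Interferon genes were found at the same 3-gene line in 0.588%, 0.692%, 36.4%, 37.2%, 22.0% and 4.22% of cells (3.07%, 7.32%, 76.0%, 76.1%, 66.4% and 36.8% without thinning). Immediate-early genes were found in 5.69%, 18.6%, 5.62%, 12.1%, 68.6% and 84.4% (55.6%, 76.5%, 52.6%, 58.2%, 91.5% and 96.9% without thinning). The D9 and D13 groups thus carried immediate-early RNA in most of their cells, beside the lists that differ between them and D7. With 1 library per day, a difference in culture or handling of these libraries cannot be told apart from the day.

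**Figure D3:**
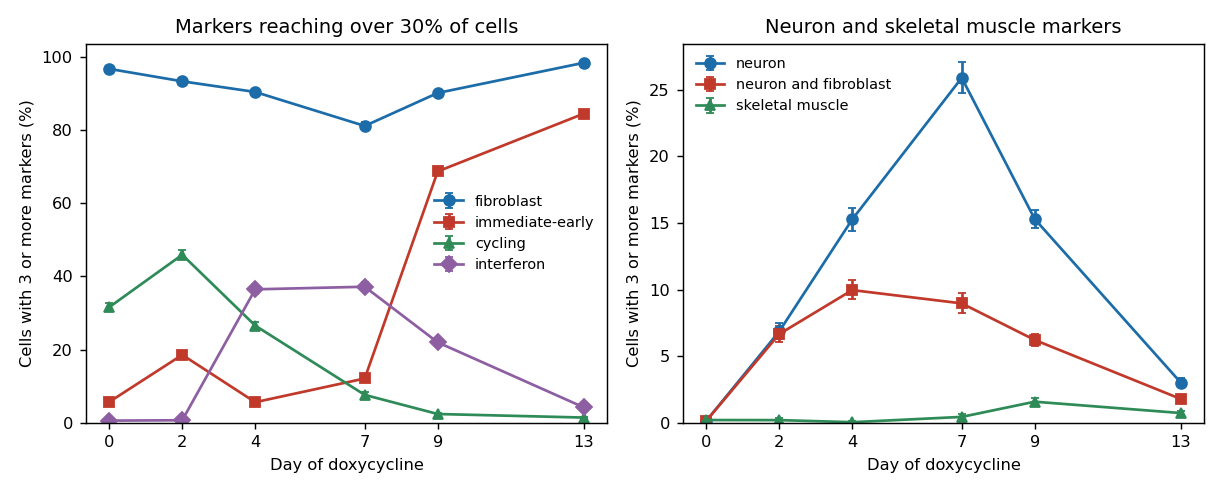
Percent of cells with at least 3 markers of a class after thinning to 3000 UMIs, against day, with exact binomial intervals (counting error only). Neuron-marker cells peak at day 7 (25.9%), immediate-early cells reach 84.4% at day 13, and skeletal muscle cells peak at day 9 (1.58%).

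Within a day, cells in which more delivered factors were detected more often had neuron markers, in steady order from D4 on after thinning and from D2 on without it. At D7 the neuron-marker share was 0.852% with 0 factors detected, 21.6% with 1, 54.0% with 2 and 76.7% (73.4 to 79.8) with all 3. At D9 the shares were 3.36%, 48.8%, 89.8% and 95.7%, and at D4 they were 3.799%, 18.6%, 27.0% and 32.8%. At D2 the shares were 2.18%, 7.45%, 10.3% and 7.18%, but without thinning they were 14.0%, 26.8%, 39.9% and 52.7%. At D13 they were 2.18%, 8.29% and 44.7% for 0, 1 and 2 factors, the last from 47 cells. Without thinning the D7 shares were 14.8%, 26.7%, 52.1% and 85.6%, a smaller contrast, and there both factors and markers are found more often in deeper cells. Thinning gives all cells the same number of sampled UMIs but leaves differences in their own RNA content, since the median at D7 was 20445 UMIs in cells with 0 factors and 11748 in cells with 3.

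Cells with 1 factor were few for Pou4f2 and Isl1, so the factors could not all be ranked. At D7 the share with Ascl1 alone was 22.5% (20.2 to 24.9), against 2.56% (0.065 to 13.5) with Pou4f2 alone in 39 cells and 11.1% (3.11 to 26.1) with Isl1 alone in 36 cells. For Ascl1, Pou4f2 and Isl1 alone in that order, the shares were 7.83%, 5.13% and 0% at D2, 19.0%, 11.6% and 12.5% at D4, and 50.3% (47.7 to 52.8), 36.2% (25.0 to 48.7) and 31.6% (21.4 to 43.3) at D9. At D13 they were 7.56% (6.004 to 9.37), 15.5% (7.996 to 26.0) and 10.4% (5.30 to 17.8), with intervals that overlap. At D7 Ascl1 with Pou4f2 gave 53.9% and Ascl1 with Isl1 54.3%. The median Ascl1 count was also higher in those cells, 3 UMIs with Ascl1 alone, 11 and 10.5 with 1 partner and 23 with both, so the number of factors and the amount of Ascl1 are not separated. Fibroblast markers went the other way at D7, from 99.6% with 0 factors to 37.8% with 3 (99.1% to 88.2% without thinning). Cycling markers at D2 went from 59.1% to 20.8% after thinning, but without it they were 65.9% with 0 factors and 69.3% with 3.

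**Figure D4:**
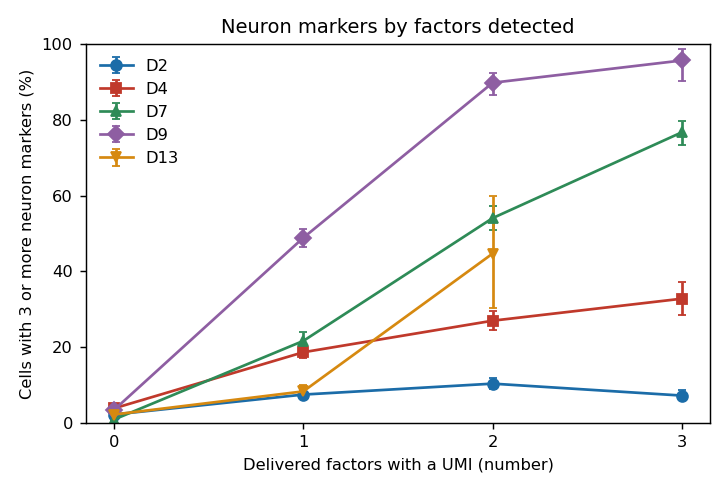
Percent of cells with neuron markers against the number of delivered factors with a UMI (0 to 3) after thinning, 1 line per day, with exact binomial intervals. The day 7 line climbs from 0.852% to 76.7% and the day 2 line stays at or below 10.3%.

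RGC identity was asked of the cells with neuron markers. RGC markers were more frequent in them than in other cells of the same library from D4 on, and after thinning most so at D9 and D13. At least 3 of 12 RGC markers were found in 41.1% (38.7 to 43.5) of D9 cells with neuron markers and in 3.17% (2.82 to 3.56) of those without. Their median depths were 17907 and 15648 UMIs, and both were thinned to 3000. The shares with and without neuron markers were 2.69% and 1.52% at D2, 20.7% and 5.63% at D4, 27.4% and 8.10% at D7 (12298 and 17980 UMIs), and 44.6% and 2.75% at D13 (33131 and 15016 UMIs). Without thinning the shares with and without neuron markers were 72.5% and 46.4% at D4, 78.4% and 53.6% at D7, 70.2% and 38.9% at D9, and 59.8% and 39.2% at D13, where the gap was then the smallest of these days. Over all cells the thinned shares were 0.827%, 1.60%, 7.94%, 13.1%, 8.97% and 4.01% in day order.

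Single RGC genes differed in how far they told the 2 kinds of cell apart at D9. Pou4f1 UMIs were found in 9.98% of cells with neuron markers against 0.265% of those without, Pou4f3 in 6.55% against 0.055%, Isl2 in 2.27% against 0.022%, and Sncg in 16.3% against 0.553%. Ebf1 (83.1% against 31.4%) and Klf7 (67.4% against 22.1%) carried most of the marker count, with Ebf3 (23.1% against 9.98%) and Nrn1 (17.0% against 6.14%). Ebf1 and Klf7 were not confined to neuronal cells. Before induction they were found in 12.5% and 25.6% of MEF cells without neuron markers. Slc17a6, the glutamate transporter of RGCs, was found in 2.14% against 0.232%. Rbpms, a pan-RGC gene, was lower in the cells with neuron markers (1.53% against 8.50%), as was Eya2 (0.184% against 0.918%), and Nhlh2 was in 0.306% against 0%.

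Within cells with neuron markers, most synaptic genes and some RGC genes were at higher levels at D13 than at D7. From D4 to D7, D9 and D13, Pou4f1 had 0.238, 0.361, 0.410 and 0.765 UMIs per 10000, Nefl 0.628, 0.715, 1.61 and 6.40, Sncg 0.598, 0.487, 0.806 and 1.84, and Slc17a6 0.007, 0.042, 0.088 and 0.359. Snap25 had 0.151, 1.03, 2.59 and 4.96, Syt1 0.620, 1.53, 2.99 and 3.48, and Gap43 1.49, 2.09, 9.24 and 15.9. Snap25, Syt1 and Gap43 are among the markers that select these cells, so their levels here are in part set by the selection. Ebf1 had 4.50, 5.45, 7.44 and 4.46, and Rbpms 0.126, 0.038, 0.052 and 0.110. Early genes were at lower levels, with Sox11 at 10.0, 12.3, 6.91 and 2.48, Dll3 at 2.20, 2.62, 1.11 and 0.333, and Hes6 at 4.37, 2.63, 1.20 and 0.457. In these cells the synaptic list, without marker genes, had a median of 1.35 for D13 over D7 (10 of 12 higher), the RGC list 0.54 (5 of 15 higher, 1 lower) and the early neurogenic list -1.59 (9 of 12 lower). The neuron-marker cells of D13 had more UMIs than others and are a different selection of cells from those of D7. In the clustering below, the neuron-like cells of D7 lay mainly in 2 clusters (18.0% and 23.9% of D7, against 1.67% in the third), while those of D13 lay mainly in the third (2.41% of D13, against 0.0266% and 0.0355%). The cells with neuron markers were not themselves counted by cluster, so how far the difference between the days is one between clusters was not shown.

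Clustering of all cells gave 18 clusters, of which 3 were neuron-like by fixed markers. Another, of 233 cells with a median of 1500 UMIs, had 12 neuron markers standing out and was left unnamed for its depth. It held 1.86% of D7 and at most 0.607% of each other day. The 3 neuron-like clusters held 0.015% of MEF, 0% of D2, 5.21% of D4, 43.5% of D7, 15.7% of D9 and 2.47% of D13. At D7 most of this came from a cluster in which only 3 neuron markers stood out (23.9% of D7), and the neuron-like share of D7 was 19.2% at resolution 0.3, 24.2% at resolution 1.0 and 24.1% with 15 components. In that cluster 2 skeletal muscle markers stood out as well, so its neuron name is weak, and the other 2 neuron-like clusters held 18.0% and 1.67% of D7. Without any marker gene in the clustering the D7 share was 43.6%, of which 24.4% of D7 was again a cluster with 3 neuron and 2 muscle markers, with Myod1 among its 10 leading genes. A muscle-like cluster of 240 cells held 1.35% of D9 and 0.665% of D13, against 0.169% of MEF and 0.124% of D7, and the D7 share was 0.638% at resolution 1.0 and 0.603% with 15 components. An epithelial-like cluster held 1.21% of MEF, 0.248% of D7 and 3.43% of D13. In it 4 epithelial, 2 fibroblast and 1 endothelial markers stood out. Its 10 leading genes included Upk3b, Upk1b, Wt1, Msln and Krt8, so the name stands for the fixed markers only. The D13 share of the epithelial-like cluster was 2.36% at resolution 1.0, 1.02% at resolution 0.3 and 0.993% without the factors. A share above that of MEF thus depended on the setting. No cluster was named epithelial-like with 15 components or without markers. Without markers, a cluster also led by Upk3b had 4 epithelial markers standing out and was left unnamed by the rule on leading genes. It held 1.17% of MEF and 1.78% of D13. A macrophage-like cluster had 23 cells, 16 of them MEF. The 2 fibroblast-like clusters held 0% of MEF and D2, 0.806% of D4, 33.7% of D7, 68.8% of D9 and 83.6% of D13 (48.4% at resolution 1.0). Most cells of MEF and D2 had fibroblast markers all the same, so cells with those markers lay in different clusters on different days, and the cluster name stands for late fibroblast-like cells. With 1 library per day, a cluster drawn mostly from 1 library was not separable from that library.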

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

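The settings without cells that had Xist and Y-linked UMIs together and without any marker gene in the clustering were added after the data had been seen, and the other settings were planned. Which of the fixed gene lists and which days have all their values given here was also decided after the data had been seen. No paired analysis was possible because each day had 1 library. No called list median changed sign: 184 of 184 alternatives to the 23 called medians had the same sign as the reported value. Over all list medians 1059 of 1200 alternatives stayed within the interval of the reported value and 141 moved. Of alternatives for shares of cells 129 of 316 stayed and 187 moved, for cell classes 79 of 120 stayed and 41 moved, and for factors 4 of 34 stayed and 30 moved. No sign changed for D13 against MEF in the neuron, fibroblast, muscle, cycling and both-kind shares, for RGC markers in cells with against without neuron markers from D2 on, or for neuron markers with the most against 0 factors. The day with the highest share did change for neuron markers, muscle markers and both kinds, and the epithelial-like share of D13 went from above to below that of MEF, as given below.

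The value added before the log moved many list medians, by its construction where genes lie below 0.5 UMIs per 10000, as many neuronal and muscle genes do. With 0.5 added, D13 over MEF gave -2.17 for contractile, 0.34 for pan-neuronal, 0.41 for synaptic, 0.26 for RGC, 0.22 for skeletal muscle, -0.57 for S-phase, -0.89 for G2/M, 0.30 for interferon and 0.72 for cAMP genes. D2 over MEF gave 0.38 for G2/M. D4 over D2 gave 0.41 for pan-neuronal and 0.92 for interferon genes, and D7 over D4 gave 0.58 for pan-neuronal and -0.61 for G2/M genes. D9 over D7 gave -0.40 for early neurogenic and 0.70 for skeletal muscle genes, and D13 over D9 gave -0.27 for interferon genes. List medians of at least 1 in size then numbered 2 for D13 over MEF (11 as reported), 1 for D2 over MEF (2 as reported) and 0 over the consecutive days (10 as reported). With 0.01 added, D13 over MEF gave 2.70 for pan-neuronal, 2.83 for synaptic and -2.90 for G2/M genes, and the numbers were 18, 5 and 20.

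Keeping genes from 0.5 UMIs per 10000 gave 2.77 for skeletal muscle in D9 over D7, and numbers of 6 for D2 over MEF and 18 over consecutive days, from fewer genes per list. Without a filter the RGC median of D13 over MEF was 0.44. Pooled sums, in which deep cells weigh more, gave 2.21 for pan-neuronal genes in D13 over MEF and 32.1 UMIs per 10000 for Ascl1 at D2 (41.2 as reported). Centring on the median gene gave 0.42 for RGC genes in D13 over MEF and 0.57 for G2/M in D2 over MEF.

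The difference of mean natural log values is on another scale, in ln units. It left several medians further from the reported values than an added 0.5 did, such as the pan-neuronal and synaptic ones of D13 over MEF, and numbers of medians past 1 were not computed for it. D13 over MEF gave -1.46 for contractile, 0.0582 for pan-neuronal, 0.08775 for synaptic, 0.0298 for RGC, 0.0151 for skeletal muscle, -0.18 for S-phase, -0.26 for G2/M, 0.0670 for interferon, -0.39 for glycolysis and 0.19 for cAMP genes. D2 over MEF gave -0.96 for contractile, 0.14 for G2/M and 0.07203 for cAMP genes. D4 over D2 gave 0.0811 for pan-neuronal and 0.26 for interferon, and D7 over D4 gave 0.14 for pan-neuronal and -0.19 for G2/M. D9 over D7 gave -0.10 for early neurogenic and 0.0305 for skeletal muscle, and D13 over D9 gave -0.21 for pan-neuronal and -0.08237 for interferon genes.

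Shares of cells depended on depth and on the number of markers, as their construction requires. With 2 markers, 4 markers, 1500 UMIs and no thinning in that order, the neuron share of D7 was 35.6%, 20.9%, 20.6% and 47.7%, and the fibroblast share of D13 was 99.1%, 97.8%, 97.7% and 99.8%. The share of D7 with both kinds was 22.7%, 3.30%, 2.84% and 42.1%, and 8.12% without cells that had Xist and Y-linked UMIs. In D4 (9.96%) it was 34.8%, 1.73%, 2.34% and 49.5%. The muscle share of D9 was 2.12% with 2 markers and 4.63% without thinning. The cycling share of D13 was 2.22% with 2 markers, 1.15% at 1500 UMIs and 3.65% without thinning. RGC markers in D9 cells with against without neuron markers were 76.2% and 18.6% with 2, 18.0% and 0.625% at 1500 UMIs, and 70.2% and 38.9% without thinning. Neuron markers in D7 cells with 3 against 0 factors were 64.9% and 0.0852% with 4 markers, and 85.6% and 14.8% without thinning (76.7% and 0.852% as reported). For other markers with 3 against 0 factors, leaving out thinning changed the sign at D2 for fibroblast (89.7% and 93.4%, then 98.8% and 84.7%), cycling (20.8% and 59.1%, then 69.3% and 65.9%) and interferon markers (0.563% and 0.899%, then 9.45% and 2.56%), and at D4 for immediate-early markers (4.89% and 5.43%, then 54.8% and 50.9%). It also changed the sign for muscle markers at D9, and at D13, with 2 against 0 factors, for fibroblast, muscle and immediate-early markers. Ascl1 at D2 was in 73.3% of thinned cells against 89.0% of all. The neuron share peaked at D7 except with 2 markers or no thinning, when D4 was highest. The muscle share was highest at D9 except without thinning, when it was highest at D2 (5.45%). The day of the highest share with both kinds was D4 as reported, D2 with 2 markers, and D9 with 4 markers or 1500 UMIs. In all 8 settings cycling was highest at D2 and lowest at D13, and fibroblast markers were highest at D13 and lowest at D7.

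The neuron-like clusters held 19.2% of D7 at resolution 0.3, 24.2% at 1.0 and 24.1% with 15 components, against 43.5% as reported. At 0.3 unnamed clusters held 39.1% of D7, against 14.9% as reported, and fibroblast-like clusters 34.0% against 33.7%. The loss at 0.3 was thus matched by cells in clusters without a name. Which cells these were was not followed, and the cause at the other settings was not tested. The epithelial-like share of D13 (3.43%) was 2.36% at 1.0, 1.02% at 0.3 and 0.993% without the factors, against 1.21% or 1.20% of MEF. Removing Scrublet calls removed at most 7 cells of a library, so it tested nothing, and the mitochondrial filter had 0 genes to use. Depth limits the smallest shares: the 0 UMIs of Pou4f2 in MEF allow up to 0.0566% of cells with a detected UMI, and set no limit on cells that express it below detection.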

Other observations

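The tests of the 3 patterns here were chosen after the results were seen, and the values in the first 3 paragraphs were picked out after they had been seen.

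Cells with neuron markers differed between days beyond RGC genes. The neuropeptide gene Vgf had 0.103 UMIs per 10000 in them at D7, 3.15 at D9 and 17.8 at D13, and Scg2 reached 4.17 and Cartpt 1.001 at D13. Stmn2 had 15.5, 19.8, 30.6 and 23.1 from D4 to D13 and Tubb3 9.87, 14.1, 15.5 and 8.04, both of them among the markers that select these cells. Genes of other neuron types were present as well. Lhx3, a motor neuron gene, had 0.483, 1.34, 0.799 and 0.118, Prrxl1, a somatosensory gene, had 1.05, 1.84, 1.06 and 0.708, and Calca had 0.384, 0.090, 0.859 and 2.95. Gad1 had 0 at D13. Ascl1 itself had 24.0, 65.5, 13.0 and 1.59 in these cells. Ntrk2, among the most raised somatosensory genes at D13, had 1.56 in cells with and without neuron markers alike, so its library level was not a neuronal signal.

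The class with skeletal muscle markers was 24 cells at D7, 169 at D9 and 81 at D13. At D7 only 0.184% of cells, out of 0.442%, had 6 or more of the markers, against 1.46% out of 1.58% at D9, so the class holds a different mix of cells on each day. Mylpf, Acta1 and Myog are among the markers that define the class. Mylpf had 16.9, 169 and 228 UMIs per 10000 in them at D7, D9 and D13, and Acta1 6.93, 47.5 and 121. The muscle regulator Myog had 27.1, 19.7 and 11.0, and Hes6 8.11, 6.28 and 3.17. Ascl1 had 23.5, 2.46 and 0.211 in the same cells. In D9 over D7 their G2/M list, which shares no gene with those markers, had a median of -1.91 with 17 of 20 lower.

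Immediate-early markers at D9 were more frequent in cells with 0 factors detected (74.8%) than with 3 (17.4%), and at D2 less frequent (13.0% against 30%). Without thinning these were 94.9% and 72.7% at D9, and 46.8% and 85.1% at D2. In cells without neuron markers D13 over D7 gave 1.47 for the immediate-early list, 0.99 for the cAMP list, -1.71 for interferon, -1.58 for G2/M and -0.998 for contractile genes. In cells with neuron markers the cAMP list gave 2.07 (10 of 13 higher) and the immediate-early list 1.30.

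The neuron-marker share was 25.9% at D7, 15.3% at D9 and 3.02% at D13. All cells were thinned to 3000 UMIs for these shares, so the D13 value of 3.02% argues against lower depth as the source. Growth in number of other cells is a candidate explanation for the step from D9 to D13. It would need the odds of neuron markers to be diluted 5.80-fold within 4 days, and the share with cycling markers was at most 2.40% on these days, against 31.6% in MEF. Cell numbers were not measured, so growth and loss of neuron-marker cells cannot be told apart, and death, detachment and loss of neuronal RNA stay open and untested.

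Cells with both neuron and fibroblast markers could be cells between states, doublets, or cells with free RNA. On the assumption that the fibroblasts came from embryos of both sexes, the excess of Xist with Y-linked UMIs gave an estimated doublet part. It was 1.41% (-3.01 to 6.76) in D4 and 16.2% (8.36 to 25.1) in D7, which argues against doublets as the main source there. In D9 it was 49.2% (40.9 to 58.0), so doublets could account for a large part. The D9 cells with both kinds were deeper, at a median of 21317.5 UMIs against 16091.5 with neuron and 15616.5 with fibroblast markers only. Depth and free RNA, which could also carry these transcripts, were not separated from doublets. The intervals cover the counting error of the cells with both kinds only. For D13 (7.93%) this estimate cannot tell doublets and mixed states apart, because cells with neuron markers only already had 20.3% with both kinds of UMI. Free RNA would bring all fibroblast genes at 1 ratio to fibroblast-only cells. The ratios were taken over all cells with neuron markers, including those with under 3 fibroblast markers. They do not describe the cells with both kinds alone. Over the 11 markers with at least 1 UMI per 10000 in fibroblast-only cells, highest over lowest was 3.84 in D4 and 2.64 in D7. That argues against free RNA as the only source of fibroblast RNA in cells with neuron markers there. In D9 highest over lowest was 1.48, as free RNA or doublets would give. In D13 it was 1.66 (21.5% to 35.7%), also nearer to 1 ratio than in D4 and D7, so free RNA stays open there too. Thy1, under that level and also a neuronal gene, was left out. At D9 its level in cells with neuron markers was 254% of that in fibroblast-only cells, against 12.9% for Lum. The D4 class lies near its threshold: 9.14% of D4 cells had exactly 3 neuron markers, out of 15.3% with at least 3, and the share with both kinds was 9.96% as reported but 1.73% with 4 markers and 2.34% at 1500 UMIs. Free neuronal RNA in droplets of fibroblasts was not tested. Cells that hold fibroblast RNA while starting neuronal genes thus stay a hypothesis for D4.

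Interferon markers were found in 0.692% of D2 and 36.4% of D4. A response mainly within the cells with most factors is argued against, since the share was 16.6% with 3 factors detected and 47.0% with 0. Without thinning the contrast was smaller, at 69.6% (67.6 to 71.6) and 83.3% (81.3 to 85.2), in the same direction. These shares count cells that carry interferon-response RNA and not what set it off, so factor-expressing cells as a trigger for others stay untested. The D4 cells with 3 factors also had fibroblast markers less often (66.4% against 98.3% with 0), so factor number and cell state were not separated. Macrophages holding the transcripts are argued against by the upper bound of 0.055% of D4 cells with macrophage markers. In cells with 0 factors detected the share was also 49.0% at D7 and 24.6% at D9, against 0.899% at D2. The pattern was thus not confined to the D4 library. With 1 library per day, a difference in culture or handling between D2 and the later libraries cannot be told apart from the day. The switch to neuronal medium falls between D2 and D4 and stays open, untested.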
